A study of Mus musculus with 2 samples.

How the data were processed

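H3K4me1, histone H3 carrying a single methyl group on lysine 4, was mapped by chromatin immunoprecipitation and sequencing in hindbrain tissue of newborn mice at postnatal day 0. Per the labels, the series held 2 biological replicates, each a pool of animals of both sexes. Replicate 1 came from 15 mice, and for replicate 2 the number of mice was not given. Both libraries had a fragment size range of 300 to 500, per the labels, which gave no unit. Since the labels named the replicates as separate tissue samples of the same group, no comparison between conditions could be made, and every value describes these 2 pools.

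The deposited files used were 4 lists of intervals on the mouse genome build mm10. Per the deposited file notes, the list of each replicate was called from its filtered alignments with a control alignment as the other input. The pooled list was called from both alignments together, and the replicated list was derived from the pooled list and the 2 replicate lists. The aligner, the peak caller and the rule for a replicated interval were not given in the sources used here. The deposited fold enrichment of each interval, a linear ratio to the control, was the authors' value and was used only to describe, rank or filter intervals within a list. The deposited p-value and q-value of each interval were given by the authors as −log10. The lowest −log10 p was 2.05 in replicate 1 and 2.02 in replicate 2, so the lists reached down to weakly enriched intervals. The deposited display score was not used. Since peak lists hold no read counts, the sequencing depth of both replicates is unknown, and no interval that needs depth was given. Exact binomial (Clopper-Pearson) intervals at 95% cover the counting of intervals only, and neighbouring intervals are not independent.

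Gene positions came from the GENCODE M21 annotation of the same build (Ensembl release 96), with 21911 protein-coding genes on chromosomes 1 to 19, X and Y, and sequence features from the matching GRCm38 genome. Each gene had a single transcription start site (TSS), the start of its annotated gene. An interval was shared when at least 50% of its length was covered by the other replicate, and the chance level was the mean of 100 random placements on the same chromosome. An interval's context was the class of its midpoint, in the order promoter (within 1 kb of any annotated TSS), coding exon, UTR, other exon, intron and intergenic. A gene counted as marked when at least 1 replicated interval lay within 10 kb of its TSS. Replicated intervals within 1 kb of each other were joined into domains. Genes with any part of the gene within 10 kb of the 500 longest domains were taken as near a long domain.

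The 25 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 25 lists. The median covered length of a list was placed among 10000 random gene lists of the same size. Hindbrain and forebrain patterning genes, and Hox paralogs, were compared with two-sided permutation tests of 100000 resamples on covered length, adjusted over the 2 comparisons. Genes are not replicates, so these p-values describe how the intervals of these libraries fall over genes. Of the listed symbols, 1 was not found in the annotation.

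The rule for named genes took from each list the 2 members with the most covered bases and the 1 member with the fewest, with ties resolved by enrichment and then symbol. From the 3 lists defined by a symbol pattern, only the 2 members with the most were taken. It further took the gene nearest to each of the 10 most enriched replicated intervals, the genes at the 10 longest domains, and unmarked members where a list had 5 or fewer. Some genes that the rule takes are not described. Genes outside this rule are said to have been chosen after their values were seen.

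Alternatives covered stricter limits (a −log10 q of at least 2, or a fold enrichment of at least 4), other overlap rules, each replicate's list alone, the pooled list, windows of 5 and 25 kb or the gene body, at least 3 intervals per gene, a 2.5 kb promoter, domains joined within 3 kb, the 1000 longest domains, and random lists matched on gene length. Random placement outside assembly gaps and the use of autosomal genes alone were added after the data were examined.

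The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Interval sharing, the rank relation of enrichment, the gene list tests and the patterning comparison were tested on simulated data. The context folds, TSS coverage, chromosome density and long domain tests were not. Of 20000 simulated intervals with 39.3% shared, 39.4% were recovered. Of 100 simulated lists of 25 genes with 90% of members marked, 97% were called by the Fisher test over 21911 genes, as were 3% of unchanged lists. In the covered length comparison, 96% of raised lists lay above the central 95% of random lists. For the patterning comparison with 52 simulated genes, the permutation test passed in 93% of draws with a difference of 1 SD and in 5% without a difference. The simulated values were continuous and held no zeros. In the replicated list, 11 of 26 hindbrain and 14 of 26 forebrain genes were at 0. Their means differed by 230 bp, with SDs across genes of 597 and 412 bp. The 93% therefore does not apply to the real comparison.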

Results

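H3K4me1, a histone mark found at enhancers and beside promoters, was profiled in the hindbrain of mice at postnatal day 0. The hindbrain holds the developing cerebellum, pons and medulla. There was 1 group with 2 biological replicates, each a pool of newborn mice of both sexes (15 mice in replicate 1). The list of replicate 1 held 120512 intervals with a median width of 215 bp, which covered 31.8 Mb or 1.17% of the mm10 genome. The list of replicate 2 held 113048 intervals with a median width of 276 bp, which covered 38.9 Mb or 1.43%. The authors' pooled list held 114270 intervals, and their replicated list 52884 intervals with a median width of 388 bp and 24.7 Mb covered. Every replicated interval was identical to a pooled interval, and 85.5% of them overlapped intervals of both replicates, against 4.16% of the pooled intervals left out. The read depth of both libraries is unknown, so a region without an interval is described as such and not as free of the mark.

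The first comparison asked how far the replicates gave the same regions. In replicate 1, 34.1% of intervals (exact 95% interval 33.8 to 34.4%) had at least 50% of their length covered by replicate 2, and in replicate 2 it was 26.9% (26.7 to 27.2%). Random placement gave 1.58% and 1.14%, so sharing was 21.6-fold and 23.6-fold above chance. Sharing was highest among the most enriched intervals. From the 10% of intervals with the lowest to the 10% with the highest enrichment, it went from 24.0% to 61.7% in replicate 1 and from 15.9% to 53.2% in replicate 2. Mean width rose as well, from 219 to 424 bp in replicate 1 and from 270 to 582 bp in replicate 2. Chance sharing was not computed per class, so enrichment and width were not separated. Over 46757 reciprocal best-overlapping pairs, enrichment was weakly related between replicates (Spearman rho 0.204, Pearson r of log2 enrichment 0.227, across regions, which are not independent replicates). A different measure, covered length within 10 kb of the TSS, gave a Spearman rho of 0.849 across 21911 genes. Only 65.2% and 65.7% of genes had an interval there in replicates 1 and 2, and the others entered as 0. The 2 rho values are therefore not comparable. At a fold enrichment of at least 4 in both lists, 29.7% of the intervals of replicate 1 and 13.8% of those of replicate 2 were shared.

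**Figure D1:**
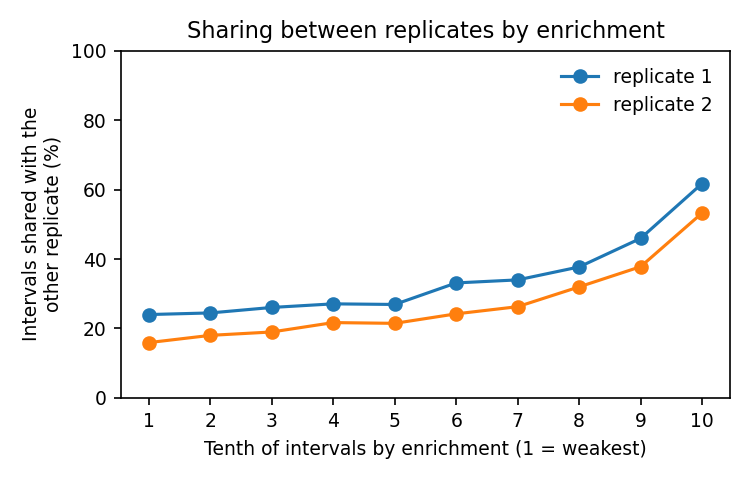
The plot shows the share of intervals of each replicate (vertical axis, percent) with at least 50% of their length covered by the other replicate, in 10 classes of equal size ordered by enrichment (horizontal axis, 1 weakest, 10 strongest). In the strongest class 61.7% of replicate 1 and 53.2% of replicate 2 intervals were shared.

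Intervals with no overlap in the other replicate numbered 66612 in replicate 1 (55.3%) and 63230 in replicate 2 (55.9%). They were narrower and less enriched in each list than the intervals that overlapped the other replicate by at least 1 bp, called shared in this paragraph. In replicate 1 the median width was 195 bp against 259 bp and the median enrichment 2.92 against 3.19. In replicate 2 the widths were 246 and 346 bp and the enrichments 3.08 and 3.38. Promoters held 14.8% of the unshared intervals in each replicate, against 22.7% and 22.8% of the shared intervals. The replicated list kept 46.3% of pooled intervals (exact 95% interval 46.0 to 46.6%), from 16.3% in the lowest of 4 enrichment classes to 88.9% in the highest.

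Replicated intervals lay mainly in introns and near promoters. Introns held 53.1% of them (exact 95% interval 52.6 to 53.5%), promoters 22.7% (22.3 to 23.1%) and intergenic sequence 19.8% (19.4 to 20.1%). Set against random placement on the same chromosomes, promoters were 3.63-fold and introns 1.34-fold above chance, while intergenic sequence was at 0.389 of its chance share. Coding exons held 1.48%, UTRs 1.23% and other exons 1.76%. In the replicate lists, promoters held 18.4% ± 0.0307 (SD, n = 2) and intergenic sequence 23.3% ± 0.0452 (SD, n = 2). The difference of the replicated list from both exceeded this spread, which rests on 2 nearly equal values. The replicated list is also a selection of the more enriched pooled intervals. Among the most enriched 10% of replicated intervals, the promoter share was 27.9%.

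The most enriched replicated interval lay in an intron of Inpp5e, which encodes an inositol phosphatase of primary cilia, on chromosome 2 from 26406860 to 26408584, 1481 bp from the TSS. Its enrichment was 8.37 in the replicated list and 7.41 ± 0.294 (SD, n = 2) in the replicates. The next lay in introns of Rara, a retinoic acid receptor gene (chromosome 11, 98928141 to 98930806, enrichment 7.19), and Cmip (chromosome 8, 117314103 to 117314994, 7.19), and 679 bp outside Ssbp3 (chromosome 4, 106909136 to 106910022, 7.19). For Rara the replicates differed most, at 7.82 and 4.42. They also differed widely for Cmip, at 7.97 and 5.23, and less for Ssbp3, at 6.11 and 7.69. Others were intronic in the receptor phosphatase gene Ptprf (7.03, with 7.17 and 5.23 in the replicates), the fatty acid desaturase gene Scd2 (6.93) and the zinc transporter gene Slc39a9 (6.86). The interval nearest to Pan2, a gene for a deadenylase subunit, was the promoter interval of this set (6.86). Intervals nearest to Ccdc187 (7.04, at 3863 bp) and Spag9 (6.86, at 32645 bp) were intergenic. Apart from Rara, Cmip, Ptprf and Ssbp3, the SD between replicates was at most 0.780 in this set.

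Around TSSs the mark formed a pair of flanks with a dip between them. Of 21911 protein-coding TSSs, 3.28% were covered at the TSS itself, 13.9% at 1100 bp downstream and 6.74% at 600 bp upstream. Coverage averaged 1.73% beyond 4.5 kb. Both replicates showed the dip, with 4.23% and 4.52% at the TSS and a downstream flank 3.07-fold and 3.63-fold higher. The contrast was stronger at CpG-rich TSSs, a split chosen after the data were examined (a CpG ratio of at least 0.6 and a GC share of at least 0.5 within 500 bp). At 9731 CpG-rich TSSs, coverage was 2.37% at the TSS and 25.1% downstream, a 10.6-fold difference. At 12180 CpG-poor TSSs it was 4.00% at the TSS and 5.49% at 700 bp downstream. No test was made, and coverage depends on the list, since the pooled list gave 5.12% at the TSS.

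**Figure D2:**
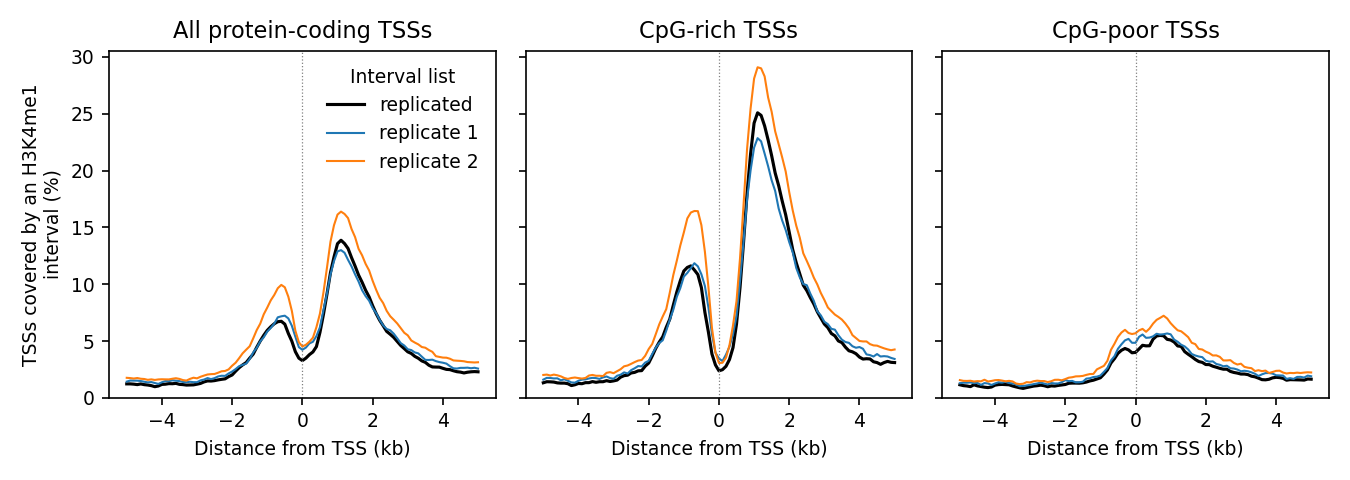
The plot shows the share of protein-coding TSSs covered by an interval (vertical axis, percent) against distance from the TSS (horizontal axis, kb, positive values downstream) for all, CpG-rich and CpG-poor TSSs, with a line for the replicated list and for each replicate. CpG-rich TSSs show the dip at the TSS and the downstream flank at 25.1%, and the highest share for CpG-poor TSSs is 7.22%, in replicate 2.

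Gene lists asked which groups of genes carried the mark. Of 21911 protein-coding genes, 11720 (53.5%) had a replicated interval within 10 kb of the TSS, and the median covered length was 257 bp. Immediate early genes, which neurons induce within minutes of stimulation, were all marked (18 of 18). So were 19 of 20 housekeeping genes, 22 of 24 Wnt pathway genes, 62 of 76 ribosomal protein genes and 20 of 24 markers of radial glia and astrocytes. These 5 lists lay above the other genes in Fisher's exact test, with adjusted p of 6.9e-05, 0.000459, 0.000438, 3.21e-06 and 0.00947 in that order. Each of the 5 was also above the other genes in each replicate's own list, with an exact test adjusted p of at most 0.0318. At a fold enrichment of at least 4, the calls of radial glia and astrocyte, Wnt pathway and housekeeping genes were lost (exact test adjusted p 1, 1 and 0.577). With at least 3 intervals per gene, the radial glia and astrocyte, Wnt and ribosomal protein calls were lost (0.154, 0.154 and 0.192, exact test), and a 5 kb window ended the radial glia and astrocyte call (0.180).

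Among immediate early genes, the transcription factor gene Junb (chromosome 8, 84974484 to 84978718) had 4997 bp covered in the replicated list and 4837 ± 67.9 bp (SD, n = 2) in the replicates. Arc, which acts in synaptic plasticity (chromosome 15, 74669083 to 74672570), had 4542 bp and 4142 ± 1162 bp (SD, n = 2). Egr1 had the fewest covered bases of the list, 377 bp, with 1101 ± 148 bp (SD, n = 2) in the replicates. In the Wnt pathway, which sets cell fate and growth, the feedback inhibitor gene Axin2 had 3982 bp and the beta-catenin gene Ctnnb1 1842 bp, and Tcf7l1 and Wnt3a had no replicated interval. The RNA polymerase II subunit gene Polr2a (3829 bp) led the housekeeping genes, where Psma1 had none. Rpl18 (5272 bp) and Rpl19 (3422 bp) led the ribosomal proteins. Among radial glia and astrocyte markers, the Notch target gene Hes5 had 4125 bp and the glutamate transporter gene Slc1a2 2416 bp. The unmarked members were the water channel gene Aqp4 and Gja1, Id4 and Slc1a3, of which Slc1a3 still had 742 and 1465 bp covered in the replicate lists.

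The median covered length set 5 lists above the central 95% of random lists. They were immediate early (median 1470 bp, percentile 100), Notch pathway (1230 bp, percentile 100), housekeeping (1055 bp, percentile 99.9), ribosomal proteins (804.5 bp, percentile 100) and Wnt pathway (720 bp, percentile 98.3). Radial glia and astrocyte markers, called by the Fisher test, reached percentile 94.5. In the replicate lists they were at 97.1 in replicate 1, inside the central range, and at 99.3 in replicate 2, above it. The Notch pathway, which balances progenitors and neurons, had 17 of 22 members marked, and its adjusted p of 0.0644 in Fisher's exact test missed the threshold. Hes5 and the coactivator gene Maml2 (3875 bp) led it. Its unmarked members were Jag2, Maml3, Notch1, Notch2 and Rbpj, although Jag2 had 1427 and 986 bp and Notch1 635 and 1705 bp covered in the replicate lists. In those lists the Notch pathway was above the other genes, with 21 and 20 of 22 members (exact test adjusted p 0.00568 and 0.0242). Wnt pathway genes fell inside the central range with a 5 kb window (percentile 90.3), a 25 kb window (94.0), the gene body (97.4), autosomal genes alone (97.3), a −log10 q of at least 2 (96.9) and a fold enrichment of at least 4 (49.9). The list of replicate 2 alone set 8 lists above that range.

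The 6 lists of granule lineage, Purkinje, hindbrain patterning, pan-neuronal, Sonic hedgehog and brainstem genes did not pass in the replicated list. Cerebellar granule lineage genes had 16 of 25 marked (adjusted p 0.473, Fisher's exact test), led by the cyclin gene Ccnd1 (3096 bp) and the hedgehog coreceptor gene Boc (2999 bp). Atoh1, which specifies granule cells, had no replicated interval but 487 and 786 bp covered in the lists of replicates 1 and 2. Purkinje and cerebellar GABAergic genes also had 16 of 25 marked, with the same exact test adjusted p, with 1655 bp covered at Kirrel2 and none at Calb1. With the gene body in place of the window, Purkinje genes passed above the other genes (log2 odds 2.18, adjusted p 0.00505, exact test). Hindbrain patterning genes had 15 of 26 marked (0.832 by the exact test), led by the isthmic signal Fgf8 (1848 bp) and by Gbx2 (1529 bp), which limits the anterior hindbrain. Pan-neuronal genes had 12 of 21 (0.901 by the exact test), led by the tubulin gene Tubb3 (2366 bp) and Ncam1 (1648 bp), with none at Dcx. The Sonic hedgehog pathway, which drives growth of granule cell precursors, had 12 of 17 (0.373 by the exact test), and its unmarked members were Cdon, Gli3, Kif7, Mycn and Smo. Brainstem motor and monoaminergic genes had 8 of 22 (0.240 by the exact test), led by the monoamine transporter gene Slc18a2 (1099 bp) and the serotonergic factor gene Fev (1087 bp), with none at Chat.

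The replicate lists, which hold more intervals, set 10 lists above the other genes in replicate 1 and 11 in replicate 2, against 5 in the replicated list. Hindbrain patterning genes were above the other genes in both, with 24 of 26 marked in replicate 1 (adjusted p 0.00836, exact test) and 23 of 26 in replicate 2 (0.0242). The same held for Purkinje and GABAergic genes, with 23 and 22 of 25 (0.00836 and 0.0318, exact test), and for pan-neuronal genes, with 19 and 20 of 21 (0.0343 and 0.00827, exact test). In the pooled list Purkinje genes passed (adjusted p 0.0365, exact test), but hindbrain patterning (0.0664) and pan-neuronal genes (0.213) did not. Granule lineage genes passed in replicate 2, with 23 of 25 (0.0137, exact test), and in the pooled list (0.0365), but not in replicate 1, with 21 of 25 (0.0960). Hedgehog pathway genes passed in replicate 2, with 16 of 17 (0.0232, exact test), and in the pooled list (0.0227), but not in replicate 1, with 15 of 17 (0.110). Whether the replicates differed in these calls was not tested. The calls were also not set against random lists matched on CpG class, so CpG-rich promoters stay open as a cause. In the replicated list, hindbrain patterning genes had 57.7% marked against a matched mean of 69.3%, and Purkinje genes 64% against 65.3%. Pan-neuronal genes had 57.1% against 59.0%, while granule lineage (64% against 62.0%) and hedgehog genes (70.6% against 67.3%) lay above. Each stayed inside the central range of matched lists.

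Other cell types gave a mixed picture. Oligodendrocyte lineage genes had 12 of 21 marked (adjusted p 0.901, Fisher's exact test), led by Sox8 (1783 bp) and the myelin gene Cnp (1451 bp), with none at Bcas1. At a fold enrichment of at least 4 they were below the other genes (log2 odds -3.59, adjusted p 0.0320, exact test). Vascular genes had 13 of 21 (0.678, exact test), led by the endothelial factor gene Sox18 (2586 bp) and the lipid transporter gene Mfsd2a (2007 bp), with none at Cdh5. They passed in replicate 1, with 19 of 21 (0.0343, exact test), but not in replicate 2, with 15 of 21 (0.709), or in the pooled list (0.213). Choroid plexus and ependyma genes had 10 of 18 (1 by the exact test), led by the ciliogenesis factor gene Foxj1 (2752 bp) and Aqp1 (1519 bp), with none at Calml4. Genes of other tissues were marked in part. Erythroid genes had 8 of 15 (1 by the exact test), led by Klf1 (1745 bp) and Epor (1679 bp), with none at Alas2. Muscle genes had 9 of 20 (0.678, exact test), led by Myh7 (1963 bp) and Acta1 (1183 bp), with none at Actc1. Epidermis genes had 5 of 18 (0.0644, exact test), led by Krt1 (1454 bp) and Grhl3 (1015 bp), with none at Dsg1a. They passed below the other genes at a −log10 q of at least 2 (adjusted p 0.0336, exact test), in the pooled list (0.0437), with a 25 kb window (0.0320), with the gene body (0.0251) and among autosomal genes alone (0.0361).

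Markers of microglia, the immune cells of the brain, and of liver were each marked at 5 of 20 genes, below the other genes (adjusted p 0.0288 for each, Fisher's exact test). Csf1r (651 bp) and Runx1 (543 bp) led the microglia list and Apoa2 (692 bp) and Apoa1 (477 bp) the liver list, while C1qa and Afp had none. Liver genes stayed below in each replicate list, with 6 of 20 in both (0.00573 and 0.00603, exact test). Microglia genes did not, with 11 and 12 of 20 (0.401 and 0.709, exact test), and their call was also lost in the pooled list (0.0975, exact test). With a 25 kb window the log2 odds of both went from -1.70 to -0.74 and the calls were lost (0.356 for each, exact test). With at least 3 intervals the log2 odds were lower, at -3.00 for both, but the calls did not pass (0.154 for each, exact test). Olfactory receptor genes, silent outside sensory neurons, were marked at 9 of 1092 genes, with 413 bp at both Olfr95 and Olfr96 from a shared interval. The exact lower-tail −log10 p of that count was 355. Vomeronasal receptor genes were marked at 1 of 326 (adjusted p 1.21e-106, exact test), the gene Vmn1r4 with 589 bp. Vmn1r1, next by the naming rule, had none. The percentile of the median covered length was 0.425 for olfactory and 4.62 for vomeronasal receptors. In both replicate lists it was 0 for each, and in replicate 2 liver genes were also below the central range, at 2.44. The olfactory percentile left the low end with random lists matched on gene length (48.3), a 5 kb window (41.3), a −log10 q of at least 2 (10.3) and a fold enrichment of at least 4 (50). There the list median was still 0 and more random lists also had a median of 0, so this rise does not show more marked genes. The log2 odds of marked olfactory genes were -7.69, -7.21 and -9.35 under the last 3 settings, against -7.20 before. Marked shares were not matched on gene length. For most other lists with few marked genes a median of 0 was as low as random lists went.

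**Figure D3:**
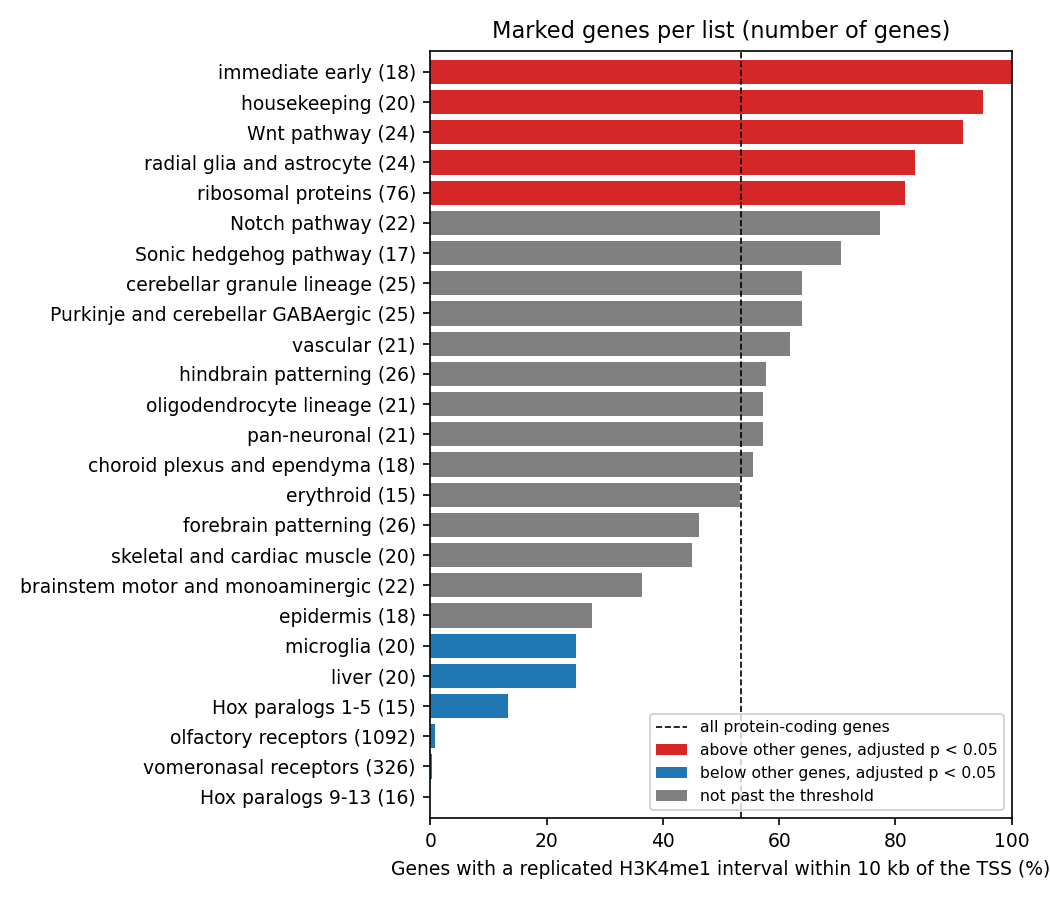
The bars show the percent of each list's genes (number of genes in brackets) with a replicated interval within 10 kb of the TSS, and the dashed line marks the 53.5% of all protein-coding genes. Red and blue bars are lists above and below the other genes at an adjusted p under 0.05 (Fisher's exact test), and grey bars did not pass.

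Hox genes, which set position along the body axis, had few replicated intervals. Of 15 genes of paralog groups 1 to 5, which are used in the hindbrain, 2 were marked, Hoxd1 (554 bp) and Hoxc4 (434 bp). Of 16 genes of groups 9 to 13, used in the trunk, none was marked. Both lists were below the other genes (adjusted p 0.00872 and 2.98e-05, Fisher's exact test). Neighbouring Hox genes share windows, and the exact tests of both lists, here and below, count them as separate genes. Their p-values are therefore too small to be taken at face value. Replicated intervals covered 0% of the Hoxa cluster on chromosome 6 and of the Hoxb cluster on chromosome 11. They covered 0.695% of the Hoxc and 0.572% of the Hoxd cluster, against 0.906% of the genome. The replicate lists differed from this. Replicate 1 covered 1.41%, 0.876%, 1.21% and 1.43% of the Hoxa, Hoxb, Hoxc and Hoxd clusters, against 1.17% of the genome. Replicate 2 covered 1.046%, 0.386%, 0.501% and 1.49%, against 1.43%. In the replicate lists, 9 and 6 of the 15 anterior genes were marked and the call was lost (adjusted p 0.816 and 0.0834, exact test). It was also lost in the pooled list (0.787, exact test), at a fold enrichment of at least 4 (0.379) and with at least 3 intervals (0.293). Among posterior genes 3 and 5 of 16 were marked there, still below the other genes (0.000946 and 0.0161, exact test). The posterior call was lost at a fold enrichment of at least 4 (adjusted p 0.0873, exact test) and with at least 3 intervals (0.192). Hoxa10 and Hoxa11 had no covered bases in the replicated list or in either replicate. Windows were placed at annotated gene starts, so some anterior windows cover central or posterior parts of a cluster. The start of Hoxc5 (102967443) lies beside that of the posterior gene Hoxc10 (102966796). That of Hoxa3 (52213336) lies between Hoxa6 and Hoxa7, and Hoxd3 and Hoxd4 have nearly the same start (74711927 and 74711929). The anterior counts are limited by this.

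Anterior and posterior Hox genes were also compared directly. Mean covered length was 65.9 bp at the 15 anterior and 0 bp at the 16 posterior genes, a difference of 65.9 bp (SE 45.3). The permutation p was 0.226 (adjusted 0.226). With 13 of 15 anterior and 16 of 16 posterior genes at 0, this test could not have passed. Every gene with covered bases was already anterior, so no conclusion was drawn from this p-value. In the list of replicate 1 the means were 307 and 39.2 bp, and the difference of 268 bp (SE 87.4) passed (permutation p 0.00257, adjusted 0.00514). In replicate 2 the difference was 82.0 bp (SE 82.9; permutation p 0.344, adjusted 0.344), so the call rested on replicate 1. The pooled list gave 227 bp (adjusted p 0.005, permutation test). Neighbouring Hox genes share windows, so these genes are not independent. Some anterior windows also cover central or posterior sequence, so the comparison does not fully separate the groups.

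Hindbrain patterning genes were compared with forebrain patterning genes, 26 in each list. Mean covered length was 510 bp at hindbrain and 281 bp at forebrain genes, a difference of 230 bp (SE 142) that did not pass (permutation p 0.114, adjusted 0.226). The replicates gave differences of 277 bp (SE 141) and 206 bp (SE 154), with permutation p of 0.0542 and 0.187. Of the forebrain genes 12 of 26 were marked (adjusted p 0.695, Fisher's exact test), led by the cortical factor genes Bcl11b (1657 bp) and Emx1 (997 bp). Hindbrain genes had the higher mean in each of these lists, and the difference was larger in the pooled list (350 bp, adjusted permutation p 0.0511) and with a 25 kb window (461 bp, permutation p 0.0367, adjusted 0.0733). With intervals of at least 4-fold enrichment it turned to -49 bp (adjusted permutation p 0.488).

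Density was compared between chromosomes, since the pools held both sexes. The X chromosome carried 62 replicated intervals, or 0.379 per Mb, against an autosomal median of 23.3 per Mb with a range from 14.2 on chromosome 3 to 38.6 on chromosome 11. This was 61.4-fold lower than the autosomal median. How the control was matched or filtered on this chromosome is not given in the sources used here, so the fold describes the deposited lists. In the longer lists of replicates 1 and 2 the X density was 2.24 and 2.30 per Mb, 23.6-fold and 21.4-fold below the autosomal median. Of 948 X genes 33 (3.48%) were marked, against 43.7 to 67.7% per autosome. The strongest X interval had an enrichment of 4.02, and each autosome reached at least 6.19. The X-linked housekeeping genes Pgk1 (692 bp) and Hprt (526 bp), named after their values were seen, were among those marked. The list members Dcx and Alas2 lie on this chromosome. The Y chromosome, with 183 genes, had 0 intervals in the replicated list, in the pooled list and in each replicate list.

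**Figure D4:**
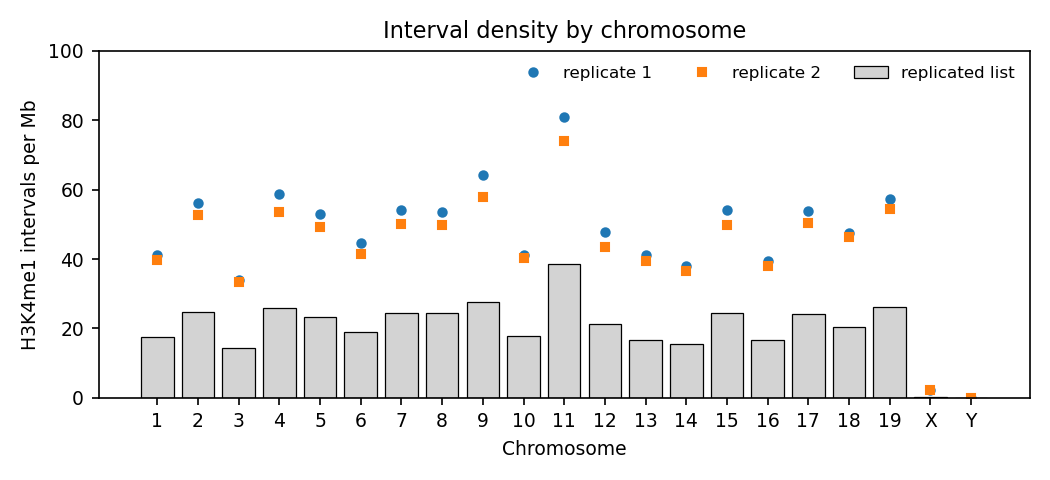
Bars show replicated intervals per Mb of sequence without gaps on each chromosome, and points show the lists of replicate 1 (circles) and replicate 2 (squares). The autosomes range from 14.2 to 38.6 replicated intervals per Mb and the X chromosome is at 0.379.

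Joining replicated intervals within 1 kb gave 38212 domains, and the 500 longest were at least 3697 bp long. The longest, 22764 bp on chromosome 14 from 25461549 to 25484312, lay in Zmiz1, a gene for a transcriptional coregulator. A further domain of 15164 bp (25486708 to 25501871) lay in the same gene. Replicates 1 and 2 covered 11922 and 13351 bp of the longest domain. Next were Zmynd8, a chromatin reader gene (15122 bp, chromosome 2, 165873677 to 165888798), Cxxc5 (13768 bp, chromosome 18), the kinase gene Map4k4 (13246 bp, chromosome 1) and Ahdc1 (11269 bp, chromosome 4). A domain of 11048 bp on chromosome 18 overlapped the gamma protocadherin cluster, including Pcdhgc5, whose products act in neuronal self-recognition. The reelin receptor gene Lrp8 (10912 bp), the chromatin remodeler gene Arid1b (10827 bp) and the adhesion receptor gene Adgrg1 (10535 bp) completed the set.

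Distance to a domain was measured from the whole gene and not from the TSS. This can favour long genes, and gene length was not matched for domains. Of 21911 genes, 492 (2.25%) lay within 10 kb of the 500 longest domains. The Sonic hedgehog pathway had 4 of 17 genes there (adjusted p 0.00499, Fisher's exact test), the granule lineage 4 of 25 (0.0109) and immediate early genes 4 of 18 (0.00499). The members of the first 2 lists were the same 4 genes, Ptch1 (a domain of 7372 bp), Gli2 (4304 bp), Boc (4005 bp) and Ccnd1 (3858 bp), so these counts are not independent. The immediate early genes were Btg2 (7873 bp), Junb (5424 bp), Dusp1 (4889 bp) and Arc (4468 bp). Ptch1, Gli2, Btg2 and Dusp1 were named after their values were seen. No olfactory or vomeronasal receptor gene lay near these domains (adjusted p 3.75e-10 and 0.00642, exact test). The granule call was lost under each of the 7 alternatives set beforehand. In the lists of replicates 1 and 2 its log2 odds were 2.81 and 2.78 against 3.197 (exact test adjusted p 0.0522 and 0.0731), and its adjusted p was 0.0623 in the pooled list and 0.399 at a −log10 q of at least 2. The hedgehog call was lost at that q limit (0.285, exact test), and at a fold enrichment of at least 4 no list was above. The list of replicate 1 alone set 5 lists above the other genes, and with joining within 3 kb the hedgehog, granule and immediate early calls were lost while the Notch pathway passed with 4 of 22 genes (adjusted p 0.0201, exact test). Notch pathway genes, with 1 of 22 near the 500 longest domains (0.929, exact test), also passed in the lists of replicate 1 (3 of 22, 0.0419) and replicate 2 (4 of 22, 0.0108).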

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

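Random placement outside assembly gaps and autosomal genes alone were chosen after the data were examined, and the other alternatives before. Of 143 values of the main results under alternatives, 60 stayed within a tolerance or kept their call, 80 moved, 2 newly passed a test and 1 reversed. The tolerance was 1.5-fold for counts and covered Mb, so a count that stayed within it can still differ, and for other values 1 SD between replicates or the 95% interval. The SD of 2 nearly equal values is very small, so a small change can count as moved. Unless stated, the cause was not tested. Stricter limits and single lists change how many intervals enter, by construction. The read depth, unknown here, limits every statement about a region without an interval.

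With a −log10 q of at least 2, replicate 1 kept 40796 intervals (13.7 Mb) and replicate 2 kept 41315 (18.5 Mb), with 25192 and 26640 without any overlap. The Spearman rho was 0.154, the replicated share 63.2%, the promoter share 23.1%, the intergenic share 19.4% and TSS coverage 2.998%. The X density was 77.7-fold below the autosomal median, 1 list, immediate early genes, was above at the longest domains and 0 lists lay below the central range of covered length. With a fold enrichment of at least 4, replicate 1 kept 8830 intervals (3.98 Mb) and replicate 2 kept 14244 (7.97 Mb). Of these 5739 and 11218 were without any overlap, and 13.8% of replicate 2 was shared by at least 50% of the length. The rho was 0.119, the replicated share 98.1%, and the promoter, intron and intergenic shares 27.4%, 52.1% and 15.7%. TSS coverage was 0.812%, with flanks of 5.24% downstream and 1.97% upstream, and the X fold 720, from 1 X interval. There 3 lists were above by marked genes, 2 above and 0 below by covered length, and 0 above at the longest domains. The hindbrain minus forebrain difference turned to -49 bp (adjusted permutation p 0.488). Housekeeping, Wnt pathway and ribosomal protein genes were then at percentiles 49.7, 49.9 and 50 of covered length, because the list medians were 0. The rule that read the first 2 as a move and not a reversal was set after they were seen.

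An overlap of 1 bp gave shares of 44.7% and 44.1%, and a reciprocal overlap of 50% gave 18.7% and 20.0%, with a rho of 0.285 over such pairs. A 2.5 kb promoter gave promoter, intron and intergenic shares of 38.9%, 40.9% and 17.9%. Placement outside gaps gave folds of 3.54, 1.30 and 0.399 in that order. The pooled list gave shares of 19.9%, 53.9% and 22.0%, TSS coverage of 5.12%, flanks of 17.8% downstream and 10.2% upstream, and an X fold of 40.5. It set 9 lists above by marked genes and 2 below by covered length, and its Hox difference passed at 227 bp (adjusted permutation p 0.005).

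In the lists of the single replicates, promoter shares were 18.3% to 18.4%, intron shares 54.0% to 54.3% and intergenic shares 23.2% to 23.3%. TSS coverage was 4.23% to 4.52%, downstream flanks ranged from 12.998% to 16.4% and upstream flanks ranged from 7.23% to 9.94%. The X fold was 21.4 to 23.6, and the Hox difference 82.0 to 268 bp. Lists above by marked genes numbered 10 to 11, lists above and below by covered length 7 to 8 and 2 to 3, and lists above at the longest domains 3 to 5.

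With at least 3 intervals, 3 lists were above by marked genes (immediate early, housekeeping and, newly, the Notch pathway) and 2 below. Lists below by covered length numbered 0 with a 5 kb window and with random lists matched on gene length, and 2 with a 25 kb window, the gene body and autosomal genes alone. In the first 2 of these settings the olfactory median stayed at 0 and tied with more of the random lists. Joining within 3 kb set 1 list above at the longest domains, the Notch pathway, and none of the 3 called lists passed.

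Of 250 log2 odds of marked genes, 175 kept their call, 27 newly passed, 21 no longer passed and 27 reversed, all in lists without a call in the replicated list. The Notch pathway accounts for 9 of those newly passing. With a fold enrichment of at least 4 the reversed values were -0.91 for hindbrain patterning, -0.42 for Purkinje, -1.13 for pan-neuronal, -3.59 for oligodendrocyte, -0.12 for vascular and -1.71 for choroid plexus genes, of which the oligodendrocyte value passed (adjusted exact p 0.0320). At a −log10 q of at least 2, erythroid genes were at 0.11. With a 5 kb window, granule genes were at -0.028, pan-neuronal and oligodendrocyte genes at -0.048 and choroid plexus genes at -1.21. With a 25 kb window, brainstem genes were at 0.036 and pan-neuronal genes at -0.067. With at least 3 intervals, Purkinje genes were at -0.33 and oligodendrocyte genes at -0.043. The gene body gave -0.20 for choroid plexus genes, and autosomal genes alone -0.057 for choroid plexus and 0.27 for erythroid genes. The pooled list gave 0.46 for forebrain and 0.43 for brainstem genes. In the single replicates, forebrain genes were at 0.19 to 1.06, brainstem genes at 1.11 to 1.13, muscle genes at 0.22 to 0.25 and choroid plexus genes at -0.63 (replicate 2) and 0.78 (replicate 1).

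Of 250 covered length percentiles, 222 kept their side and 28 moved. Of 40 domain values, 28 kept their call and 12 lost it. Of 395 covered lengths of named genes, 236 stayed within the spread between replicates and 159 moved.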

Other observations

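The tests of matched bins, of X enrichment and of the most enriched intervals were chosen after the result was seen. The tests of escape genes, nearby intervals and CpG classes were set before their own result, on patterns found in these data.

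Genes with a CpG-rich TSS were marked more often than others, a class not described by the lists. Of 9731 such genes 7547 (77.6%) had a replicated interval within 10 kb, against 4173 of 12180 CpG-poor genes (34.3%). The X genes with the most covered bases were Idh3g, a subunit of a mitochondrial dehydrogenase, and its neighbour Ssr4, with 1260 bp each, chosen after their values were seen. The synaptic vesicle gene Syn1, chosen in the same way, had 252 bp.

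The X chromosome carried few replicated intervals. Base composition, repeats and gene density went with part of this but not the whole, since autosomal bins of 100 kb held 2.20 intervals on average and 0.747 after matching, which was still 19.7 times the 0.0380 of X bins. A lower dose of marked X chromosomes in pools of both sexes, against a background not lowered alike, stays open. In the pooled list X intervals had 0.587 of the median enrichment of as many strongest autosomal intervals per Mb. The X median was 2.85, against 4.85 for those and 3.01 for all autosomal intervals. The ratio sets all X intervals against only the strongest autosomal ones, so fewer X intervals of unchanged enrichment would also lower it. Any cause that lowers X enrichment would do so too. The criterion was revised after this value was seen, and no conclusion was drawn from the ratio. Silencing of 1 X chromosome in female cells cannot be told apart from other causes, with 0 of 10 escape genes listed by hand marked against 33 of 938 others (exact p 1), and 4 of 10 against 14.1% in replicate 1 (exact p 0.0424) and 3 of 10 against 15.5% in replicate 2 (exact p 0.195). The 0 of 10 met the bound set beforehand against silencing, a share at or below that of other X genes. With 3.52% of the others marked, 0 of 10 could not pass a test as lower, so no conclusion was drawn from it. The handling of the control on this chromosome could not be tested, and no biological explanation could be set against the dose, because no group held a single sex.

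The replicates shared a limited part of their intervals. Of the most enriched 10%, 74.96% in replicate 1 and 78.6% in replicate 2 overlapped the other replicate by 1 bp, against 33.6% and 28.9% of the least enriched 10%. These shares lay between the bounds set for and against a permissive threshold. Limiting both lists to a −log10 q of at least 2 did not raise sharing, with 30.99% and 22.3%. Nor did a fold enrichment of at least 4, with 29.7% and 13.8%. Such limits also remove partners just below them and shorten the covered length. The chance level was not recomputed, so these shares cannot decide. Of intervals without any overlap, 43.7% and 44.4% lay within 1 kb of the other replicate, 2.21 and 2.25 times the share after a 20 kb shift. These ratios also lay between the bounds for different edges of the same marked region. Both stay open, a difference in depth could not be tested without read counts, and no biological explanation was tested.

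Gene lists differed in their share of marked genes, and lists differ in CpG-rich promoters. Of the 11 called lists, 9 stayed outside the central 95% of random lists matched on CpG class, which argues against CpG class as the whole cause for these. The Hox lists are among them, and since their genes share windows, the central range may be too narrow for those lists. Microglia and liver genes fell inside, so their low share stays open to it. Only the replicated list was matched in this way, so calls made only in the replicate or pooled lists or under other settings stay open to CpG class. No biological explanation was tested for any of these lists.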
